A study of Homo sapiens with 15 samples.

How the data were processed

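Gene expression was measured in human lymphoid cell lines on Affymetrix U133 Plus 2.0 oligonucleotide arrays, with total RNA extracted with a commercial kit (RNeasy) and labelled with biotin, per the labels' protocols. The series holds 15 arrays of 9 cell lines. Per the labels, 6 lines (10 arrays) come from classical Hodgkin lymphoma: L428, L1236, KM-H2, HDLM2, L540 and L540Cy. The other 5 arrays are Namalwa (Burkitt lymphoma), SU-DHL-4 (B cell non-Hodgkin lymphoma) and Reh (B cell acute lymphoblastic leukaemia). Per the series design text, 6 lines were hybridised as biological duplicates and 3 lines (L540, L540Cy and SU-DHL-4) once.

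The deposited values are log2 signals per probe set made by the authors with RMA (robust multi-array average, which corrects background, normalizes between arrays and summarises probes), per the submitters' processing notes. The software, its version and its settings are not given in the sources used here. The medians of the 15 arrays lay between 5.50 and 5.56, and the upper quartile was 7.30 in Namalwa replicate 2 against 7.53 to 7.71 in the other arrays. RMA compresses differences near the background, so the fold change of a gene that is dim in one group is understated. For arrays of this kind the number of arrays limits the precision, and no count or depth applies.

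The table has 54675 probe sets. The 62 control probe sets were left out. Of the rest, 41091 had 1 gene symbol in the platform annotation, 1801 had several and 11721 had none there, and only the first kind was used. Symbols were checked through the Entrez identifier against a RefSeq gene table (assembly GRCh38.p14): 41037 probe sets matched and 0 were renamed. A further 59 probe sets of sex-linked markers were left out. A gene was represented by its probe set with the highest mean over all arrays, which left 19740 genes, 10511 of them with over 1 probe set. No filter on dim genes was applied. The files name no genome build, so no coordinates are printed. Some genes that belong to the lists below were not analysed here.

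In the main comparison the cell line was the replicate. Arrays of a line were averaged, and L540 was averaged with L540Cy, which is known from background as its subline, so that 5 Hodgkin lines stood against 3 non-Hodgkin lines. Differences were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The word called is used for genes past this threshold. Differences are on the log2 scale, as Hodgkin minus non-Hodgkin.

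A total of 26 gene lists were tested on the same line means with camera of limma at a preset inter-gene correlation of 0.01, adjusted over the 26 lists. The same test with an estimated correlation, and fry, were alternatives. Several genes, such as BATF3, GATA3, CCR7, CCND2 and FAS, belong to more than 1 list, so the lists are not independent.

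Differences between single lines came from a limma fit of all 15 arrays with 1 mean per cell line. Its spread, with 6 residual degrees of freedom, comes from the 6 lines with 2 arrays, and lines with 1 array were assumed to vary like them. These p-values therefore measure the spread between cultures of a line, and they compare lines, not diagnoses. An F test asked which genes differed among the 5 Hodgkin lines of origin. Each Hodgkin line was set against the mean of the other 4, L540Cy against L540, and the 3 non-Hodgkin lines against one another.

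Samples, comparisons, gene lists, alternatives and the rule for named genes were fixed before the data were examined. In the main comparison the rule took the 12 largest rises and 12 largest falls among called genes whose 5 Hodgkin lines all lay on one side of the 3 non-Hodgkin lines. For each list it took up to 3 called members in each direction, or, where none was called, the 2 with the largest difference, as values only. For every contrast between lines it took the 5 largest rises and 5 largest falls. Fixed markers were named whatever the values, among them TNFRSF8, FUT4, CSF1R, MAML2, CD79A, CD79B, MS4A1, PAX5, EBF1, CD3D and CD3E. List members named in the comparisons between single lines were chosen after their values were seen.

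The alternatives counted L540 and L540Cy as 2 lines, left out L540Cy, fitted arrays with the line as a random block (duplicateCorrelation), with and without the replicate number, and used the mean of all probe sets or the most variable one. They also filtered dim genes at a log2 signal of 6 or at the median, normalized or centred the arrays again, used trend and robust variance, asked for a difference of at least 1 log2, and left out each line or each duplicated array in turn. Chosen after seeing the data were the removal of Reh replicate 1, Namalwa replicate 2 or L540, the gene lists under both scalings, and the 12 numbered arrays without a replicate block for the line contrasts.

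The fits were tested on simulated data with 200 changed genes among 19740. For the comparison of Hodgkin with non-Hodgkin lines, 73.1% of changes of 2 log2, 85.1% of changes of 4 log2 and 95.5% of changes of 6 log2 were recovered, with 10 false calls. For L540Cy against L540 the shares were 76.1%, 97.0% and 98.5%, with 9 false calls. For L428 against the other Hodgkin lines they were 94.0%, 100% and 100%, with 4 false calls. For the F test among the Hodgkin lines, 188 of the 200 genes were recovered with 6 false calls. Of the 26 lists, the 1 list shifted by 2 log2 passed and 0 others did. The simulated genes varied independently, each with the same spread in all lines. This run therefore cannot show how often lists of genes that move together pass by chance. Estimated correlations in the real lists reached 0.409 for MHC class I and 0.595 for MHC class II genes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for tables and plots.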

Results

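The expression profiles of 6 cell lines derived from classical Hodgkin lymphoma were set against those of 3 lines from other B cell malignancies. Hodgkin and Reed-Sternberg cells, the tumour cells of Hodgkin lymphoma, descend from B cells in most cases. Of the lines, L428, L1236 and KM-H2 are known from background as B cell derived and HDLM2 and L540 as T cell derived, so the comparison with B cell lines also crosses lineages. Namalwa is a Burkitt lymphoma line, SU-DHL-4 a B cell non-Hodgkin lymphoma line and Reh a precursor B cell leukaemia line. Duplicate arrays of a Hodgkin line differed by an SD of 0.24 to 0.36 log2 over all genes (n = 4 lines). The SD was 0.52 log2 for Namalwa and 0.62 log2 for Reh, and 0.54 log2 between the arrays of L540 and L540Cy. The array labelled Reh replicate 1 stood apart from Reh replicate 2 in genes otherwise found in SU-DHL-4. Over 22 genes that SU-DHL-4 expressed over 3 log2 above all other arrays, Reh replicate 1 set aside, Reh replicate 1 exceeded Reh replicate 2 by a median of 3.995 log2. Several counts are therefore also given without that array.

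The first comparison asked which genes separate Hodgkin from non-Hodgkin lines. The largest rises in the Hodgkin lines were those of CCND2 (cyclin D2), CCR7 (a chemokine receptor of lymphocyte homing) and IL1R2 (a decoy receptor for interleukin 1). CCND2 was 8.42 ± 0.38 log2 higher (SE, 5 lines against 3, adjusted p = 0.000103), at 12.61 ± 0.52 (SD, n = 5) against 4.18 ± 0.66 (SD, n = 3). CCR7 was 8.06 ± 0.56 log2 higher (SE, adjusted p = 0.00101) and IL1R2 7.95 ± 0.62 log2 higher (SE, adjusted p = 0.00157). PHLDA2 followed at 7.68 log2, then DHRS2 at 7.12, RUNX2 at 7.06 and the death receptor gene FAS at 6.88 log2. BATF3, a transcription factor of the AP-1 family, rose by 6.57 log2, GATA3 by 6.53, DRC9 by 6.37, the cytidine deaminase gene APOBEC3B by 6.23 and MYOF by 6.09 log2. With the mean of all probe sets of a gene in place of the brightest, PHLDA2 had 2.73, DRC9 3.61, MYOF 4.01 and RUNX2 1.27 log2, and RUNX2 was not called (adjusted p = 0.06). DHRS2 (adjusted p = 0.0482) lost its call without Reh replicate 1 (0.0558), without Namalwa replicate 2 (0.0534) and without any line but L540 (0.077 to 0.165). It also lost it without L540Cy (0.0664), with L540 and L540Cy as 2 lines (0.0624) and with the mean of all probe sets (5.79 log2, adjusted p = 0.0691). Calls also ended for RUNX2 without Reh, Namalwa or SU-DHL-4 (0.0535 to 0.0659), for MYOF without these, KM-H2 or L540 (0.0511 to 0.0849) and for APOBEC3B without Namalwa (0.0523).

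JCHAIN, which joins immunoglobulin polymers, had the largest fall, at -7.43 ± 1.06 log2 (SE, adjusted p = 0.0228). JCHAIN was at 11.84 in Reh replicate 1, 3.50 in Reh replicate 2 and 12.45 in SU-DHL-4, and without Reh replicate 1 its adjusted p was 0.251 (from 1.55e-06 to 0.251 over its alternatives). Its call also ended without any line but KM-H2 or Reh (adjusted p = 0.0517 to 0.0785). ALOX5 (leukotriene synthesis) was lower by -6.51 log2 and VPREB3 by -6.44 log2. CD79A and CD79B, the signalling chains of the B cell receptor, were lower by -6.36 ± 0.17 and -5.91 ± 0.16 log2 (SE, adjusted p = 6.01e-06 for both). CD79A stood at 5.94 ± 0.11 in the Hodgkin lines (SD, n = 5) and at 12.30 ± 0.38 in the others (SD, n = 3). The kinase genes SYK and BTK were lower by -5.48 and -5.09 log2. DOK3, APBB1IP, RALGPS2, ARL11 and NLRC3 completed the 12, between -6.04 and -5.22 log2. The call of APBB1IP ended without HDLM2, L540, Reh, Namalwa or SU-DHL-4 (adjusted p = 0.0514 to 0.0961). With the mean of all probe sets of a gene the differences were -3.18 log2 for ALOX5, -3.73 for DOK3, -3.64 for APBB1IP, -2.20 for CD79B and -2.78 for ARL11, all called.

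In total 150 genes were higher and 121 lower in the Hodgkin lines, 1.37% of the 19740 tested. Of these, 137 and 112 differed by at least 1 log2. In all 271 called genes the 5 Hodgkin lines lay on one side of the 3 non-Hodgkin lines. The calls come from the same line means, so this separation is no independent support for them. It was found in 10.7% of all genes, against 3.57% if the lines were interchangeable, a share for which no spread was estimated. At an unadjusted p under 0.05 there were 2810 genes. Without Reh replicate 1 the counts were 111 and 84, and 193 of the 271 calls held. Leaving out a line lowered the counts most for Namalwa (68 higher, 79 lower), SU-DHL-4 (71 higher) and L540 (69 lower). Among lower genes, 79 passed without L1236 and 78 without HDLM2.

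**Figure D1:**
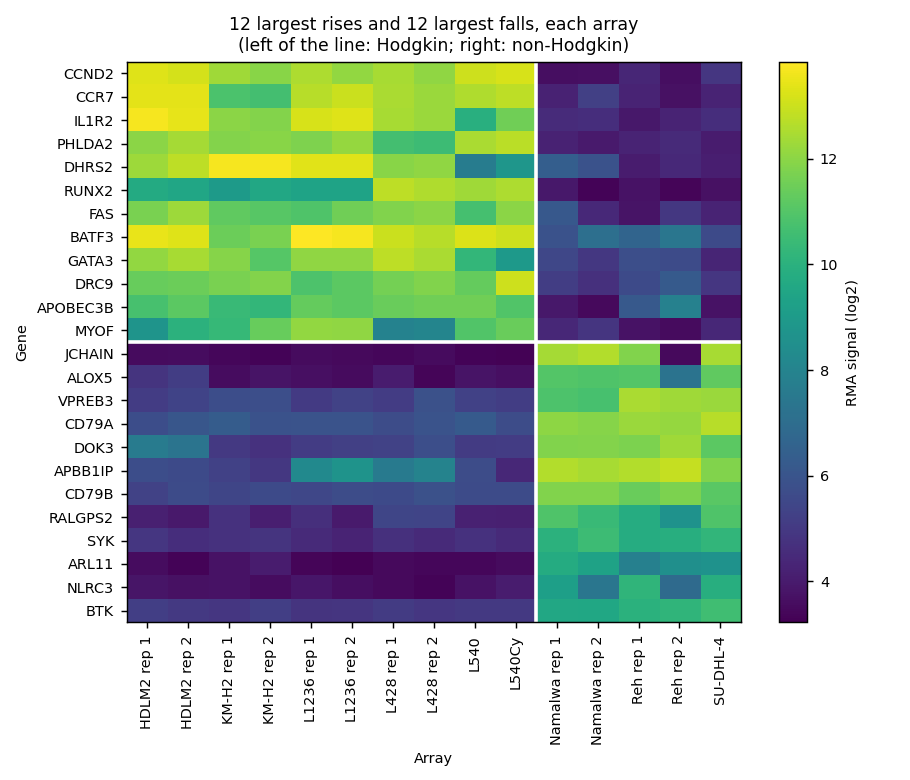
RMA signal (log2, colour) of the 12 genes with the largest rise and the 12 with the largest fall, by gene (rows) and array (columns), with the Hodgkin arrays left of the white line. In JCHAIN the arrays of Reh differ, at 11.84 in replicate 1 and 3.50 in replicate 2.

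Genes of B cell identity were lower in the Hodgkin lines. Of 29 measured members 8 fell, 0 rose and 21 did not pass, and 20 fell when adjusted over the list alone (median difference -3.70 log2, camera adjusted p = 1.18e-18, and 0.00588 with an estimated correlation). VPREB3, CD79A and CD79B had the largest falls. In the germinal centre list 3 of 12 members fell and 0 rose, 9 falling when adjusted over the list alone (camera adjusted p = 1.34e-11, and 0.00936 with an estimated correlation): MME by -5.01, CD38 by -4.34 and BACH2 by -4.17 log2. MS4A1, which encodes CD20, had a difference of -4.98 ± 1.06 log2 (SE, adjusted p = 0.0808). It was at 11.47 in Reh replicate 1 and 4.12 in Reh replicate 2, and its difference without the former was -3.76 log2. Of the 29 B cell identity genes, 12 were over 1 log2 higher in Reh replicate 1 than in replicate 2, and the list had 8 falls with or without that array. PAX5 and EBF1, transcription factors of the B lineage, had differences of -4.12 (adjusted p = 0.164) and -3.70 log2 (adjusted p = 0.186), with -2.20 log2 for PAX5 as the mean of its probe sets. PAX5 reached 10.81 ± 0.26 in L1236 (SD, n = 2 arrays), within the range of the non-Hodgkin lines.

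Plasma cell genes moved in both directions, with 1 rise, 2 falls and 7 of 10 not passing, the same when adjusted over the list alone (camera adjusted p = 0.318). IRF4 was 4.95 log2 higher (adjusted p = 0.0303). Its call ended without any line but Namalwa (adjusted p = 0.0567 to 0.0973), and its difference was 2.21 log2 with the mean of all probe sets. JCHAIN and TNFRSF17 were lower, TNFRSF17 by -4.67 log2, and both calls ended without Reh replicate 1 (adjusted p = 0.251 and 0.295). TNFRSF17 had an adjusted p of 0.0505 without Namalwa replicate 2 and of 0.0798 to 0.154 without any line but Reh. None of 14 precursor B cell and leukaemia genes passed (0 when adjusted over the list alone), although the list as a whole was lower (median -2.08 log2, camera adjusted p = 0.0021). Without Reh its median was -0.14 log2 (adjusted p = 0.0844), so the size of the fall rested on that line, and the adjusted p was 0.212 with an estimated correlation. Its members with the largest differences, IGLL1 and RAG2, had -5.42 and -3.70 log2 without passing (-1.96 for RAG2 without Reh), and 3 members were over 1 log2 lower in Reh replicate 1 than in replicate 2.

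**Figure D2:**
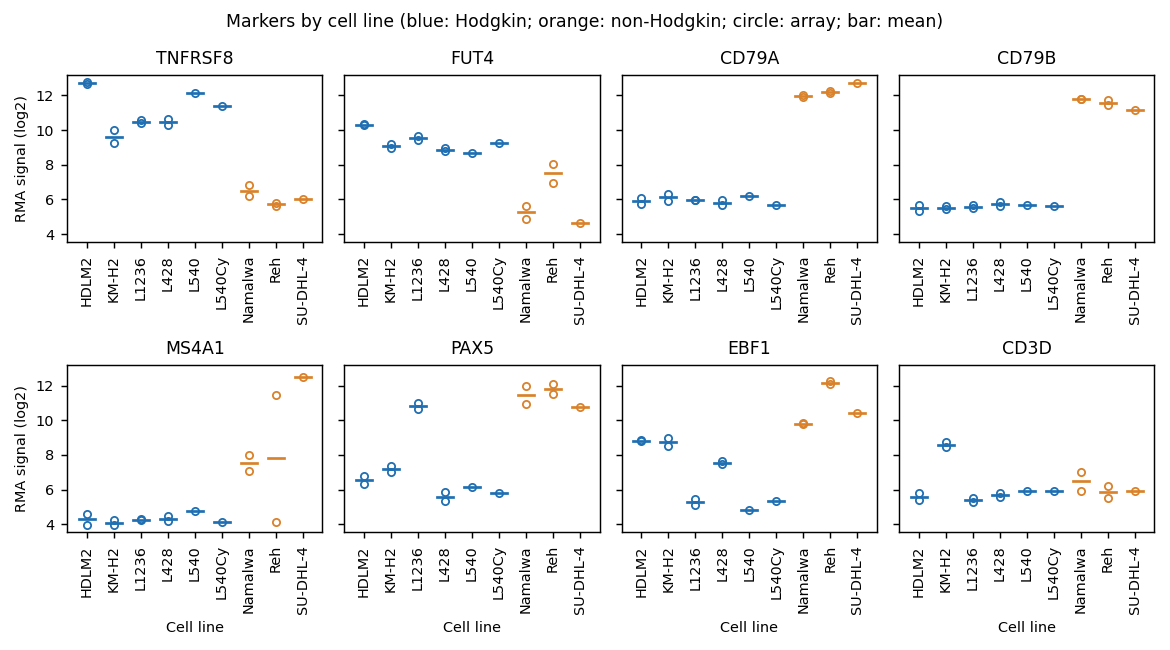
RMA signal (log2, vertical axis) of 8 marker genes by cell line, with circles for arrays and bars for line means, Hodgkin lines in blue and the others in orange. CD79A and CD79B separate the lines, while PAX5 in L1236 (10.81) lies among the non-Hodgkin lines and MS4A1 differs between the arrays of Reh (11.47 and 4.12).

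Markers of Hodgkin and Reed-Sternberg cells were higher as a group. Of 24 members 8 rose (7 without Reh replicate 1) and 0 fell, 15 rising when adjusted over the list alone (median 3.85 log2, camera adjusted p = 6.42e-19, and 0.00936 with an estimated correlation). CCR7, BATF3 and GATA3 led it. TNFRSF8, which encodes CD30, was 4.92 ± 0.68 log2 higher (SE, adjusted p = 0.0198), at 11.01 ± 1.22 (SD, n = 5) against 6.08 ± 0.40 (SD, n = 3). The call of TNFRSF8 ended without Reh (adjusted p = 0.0669), Namalwa (0.0642) or SU-DHL-4 (0.0762), and its difference stayed between 4.50 and 5.27 log2. FUT4, whose enzyme makes CD15, differed by 3.57 log2 and did not pass (adjusted p = 0.0553). It passed in 10 of its 23 alternatives, where adjusted p ranged over all of them from 0.00113 to 0.173. CSF1R differed by 1.02 log2 (adjusted p = 0.419). MAML2, a coactivator of NOTCH, was 5.10 log2 higher (adjusted p = 0.0449), a call that ended without Reh replicate 1 (adjusted p = 0.0934) and without any line but Reh (0.0591 to 0.148).

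The NF-kB, AP-1 and JAK-STAT lists rose with these markers. In the NF-kB list 7 of 29 members rose and 0 fell, 13 rising when adjusted over the list alone (camera adjusted p = 1.55e-12), led by CCND2 and by LTA and EBI3 at 5.11 log2 each. In the AP-1 list 5 of 14 rose and 0 fell, 9 over the list alone (camera adjusted p = 3.91e-10), led by BATF3, ATF3 (5.05 log2) and JUN (4.15 log2). In the JAK-STAT list 3 of 19 rose and 0 fell, 7 over the list alone (camera adjusted p = 2.72e-09): the feedback inhibitors SOCS3 (5.08 log2) and SOCS1 (3.61 log2), and STAT5A (2.51 log2). All 3 lists passed with an estimated correlation, at adjusted p = 0.00762, 0.00588 and 0.00936. LTA and SOCS3 were lost without Reh replicate 1 (adjusted p = 0.0559 and 0.0574) and without the array of L540, with L540Cy kept (0.0632 and 0.0565). Calls also ended for LTA without any line but L540 and its subline (0.0668 to 0.164), for SOCS3 without any line but L428 or KM-H2 (0.0633 to 0.155), for EBI3 without L428, HDLM2, any non-Hodgkin line or L540Cy (0.0544 to 0.0891), for STAT5A without HDLM2, L540 or any non-Hodgkin line (0.0538 to 0.0993) and for SOCS1 without Namalwa (0.0626). With the mean of all probe sets SOCS3 had 1.70 log2 and was not called (adjusted p = 0.13), while ATF3 had 2.59 and SOCS1 1.60 log2.

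Among cytokines and chemokines 4 of 32 rose (3 without Reh replicate 1) and 0 fell, with 10 higher and 1 lower when adjusted over the list alone (camera adjusted p = 3.74e-08), and IL32 was 5.39 log2 higher. Among their receptors 5 of 33 rose (4 without that array) and 0 fell, 11 over the list alone (camera adjusted p = 6.21e-08), with IL2RB 5.11 log2 higher after CCR7 and IL1R2. In the adhesion and migration list 4 of 25 rose and 0 fell, 6 over the list alone (camera adjusted p = 0.000837), with ANXA1 at 6.01, LGALS1 at 5.63 and TIMP1 at 5.30 log2. Calls ended for IL2RB without KM-H2 or any non-Hodgkin line (adjusted p = 0.0508 to 0.0951), for ANXA1 without Namalwa or SU-DHL-4 (0.0508 and 0.0553) and for TIMP1 without these or L1236 (0.0517 to 0.0819), and ANXA1 had 3.01 log2 with the mean of all probe sets. These 3 lists passed with an estimated correlation, at adjusted p = 0.0199, 0.00762 and 0.0281. In the TNF receptor family FAS, TNFRSF11A (5.93 log2) and TNFRSF9 (5.75 log2) were among 4 rises, TNFRSF17 was the 1 fall and 13 of 18 did not pass. Adjusted over the list alone it had 5 rises and 2 falls, and the list did not pass (camera adjusted p = 0.105), but it did with the arrays centred on their medians (0.0178) and with fry (0.00191). Calls ended for TNFRSF9 without any line but L428 or HDLM2 (0.0601 to 0.135), without L540Cy (0.0619) and with the mean of all probe sets (3.27 log2, adjusted p = 0.13), and for TNFRSF11A without L540 or any non-Hodgkin line (0.0501 to 0.0792).

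Antagonists of B cell transcription factors had 3 rises and 1 fall in 7 members, the same when adjusted over the list alone. GATA3, ID2 (4.24 log2) and MSC (3.91 log2) were higher and ID3 lower by -4.52 log2. ID3 was lost without Reh replicate 1 (adjusted p = 0.0541), Namalwa replicate 2 (0.0514) or the array of L540 (0.0586), and without any line but KM-H2 (0.072 to 0.161), and MSC without any non-Hodgkin line (0.057 to 0.0734). The list passed at camera adjusted p = 0.0166 (adjusted p = 0.201 with an estimated correlation, 0.0535 without KM-H2 and 0.0581 without Reh). In the interferon response list 1 of 26 rose, IFITM1 by 4.54 log2, and 0 fell, 6 rising over the list alone (camera adjusted p = 9.47e-06, and adjusted p = 0.146 with an estimated correlation). IFITM1 had adjusted p = 0.0778 without Reh replicate 1 and 0.0963 without Namalwa replicate 2, and its call ended without any line but L428 (0.0543 to 0.108). No gene of MHC class I presentation passed among 13, 1 rising over the list alone (camera adjusted p = 0.000151, and adjusted p = 0.212 with an estimated correlation), where TAP1 had 2.81 and PSMB9 1.60 log2 (1.03 without SU-DHL-4). Of 15 MHC class II genes 0 passed, also over the list alone (camera adjusted p = 0.36, and 0.0201 upward without L1236), and HLA-DQA1 and HLA-DQB1 had 3.44 and 1.19 log2. The sign of both depended on the probe set: with the most variable one they had -1.56 and -0.84 log2, and only 1 of 3 probe sets of HLA-DQA1 was higher.

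Among apoptosis regulators FAS and CFLAR (3.64 log2) rose, 2 of 21, also over the list alone (camera adjusted p = 0.0221). The adjusted p was 0.0913 with an estimated correlation, 0.0519 without L1236 and 0.16 without Namalwa. CFLAR had adjusted p = 0.0605 with its most variable probe set. In the cell cycle list CCND2 was the 1 rise in 33 members, 0 fell, and 2 rose and 4 fell over the list alone. This list was lower as a whole (median -0.29 log2, camera adjusted p = 0.0221), which was lost when arrays were normalized again (0.0556) or centred (0.0793), without L540 (0.105), Reh (0.106) or SU-DHL-4 (0.0936), and with an estimated correlation (adjusted p = 0.322). MYC and ribosome biogenesis genes had 0 calls in 15, also over the list alone, and were lower as a list (camera adjusted p = 0.011, adjusted p = 0.212 with an estimated correlation and 0.114 without Namalwa). Their largest differences, TERT and MYC, were -1.67 (-1.06 without Reh) and -1.24 log2.

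The NOTCH list had 1 rise (MAML2), 2 falls and 31 of 34 not passing, and 3 rises and 2 falls over the list alone (camera adjusted p = 0.36). DTX1 was lower by -4.14 log2 and DTX4 by -2.17 log2, and DTX4 was lost without Reh replicate 1 (adjusted p = 0.169), Namalwa replicate 2 (0.0514) or the array of L540 (0.0512) or of L540Cy (0.0538), and without any line but Reh (0.0851 to 0.156). Of chromatin modifiers 2 of 23 fell and 0 rose, also over the list alone: CBFA2T3 by -3.75 and TET1 by -2.35 log2 (camera adjusted p = 0.102). That list passed without Reh replicate 1 (0.04), KM-H2 (0.0319), Namalwa (0.0406) or SU-DHL-4 (0.0479), and ranged from 0.0315 to 0.363 over its alternatives. Of receptor tyrosine kinases 1 of 18 rose, DDR2 by 3.63 log2, and 2 over the list alone (camera adjusted p = 0.286), and the call of DDR2 ended without L1236, HDLM2, any non-Hodgkin line or L540Cy (0.0577 to 0.111).

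Markers of other cell types showed few calls. In the T cell list GATA3 and SH2D1A (4.71 log2) rose and LCK was lower by -4.79 log2, 3 of 22 and the same over the list alone (camera adjusted p = 0.472, upward, with a median of -0.02 log2). LCK was lost without Reh replicate 1 (adjusted p = 0.132) and without L1236, HDLM2, L540 or Namalwa (0.0508 to 0.0572), and SH2D1A had 2.56 log2 with the mean of all probe sets. CD3D and CD3E differed by 0.14 and -0.30 log2 (adjusted p = 0.946 and 0.439), CD3D by -0.45 to 0.35 log2 over its alternatives. No NK and cytotoxic gene passed among 16, also over the list alone (camera adjusted p = 0.537), where NKG7 and GZMB had 1.72 and 1.38 log2, and 0.43 and -0.08 log2 without L540. In the myeloid list 1 of 24 fell, SPI1 by -2.44 log2, also over the list alone (camera adjusted p = 0.168). Of 17 stromal and endothelial genes 0 passed, 1 rising over the list alone (camera adjusted p = 0.903, upward, with a median of -0.02 log2), and ACTA2 and DCN had 2.16 and -1.97 log2. Only 1 of 3 probe sets of ACTA2 was higher, their mean giving 0.70 log2, and DCN had -0.79 log2 without SU-DHL-4.

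**Figure D3:**
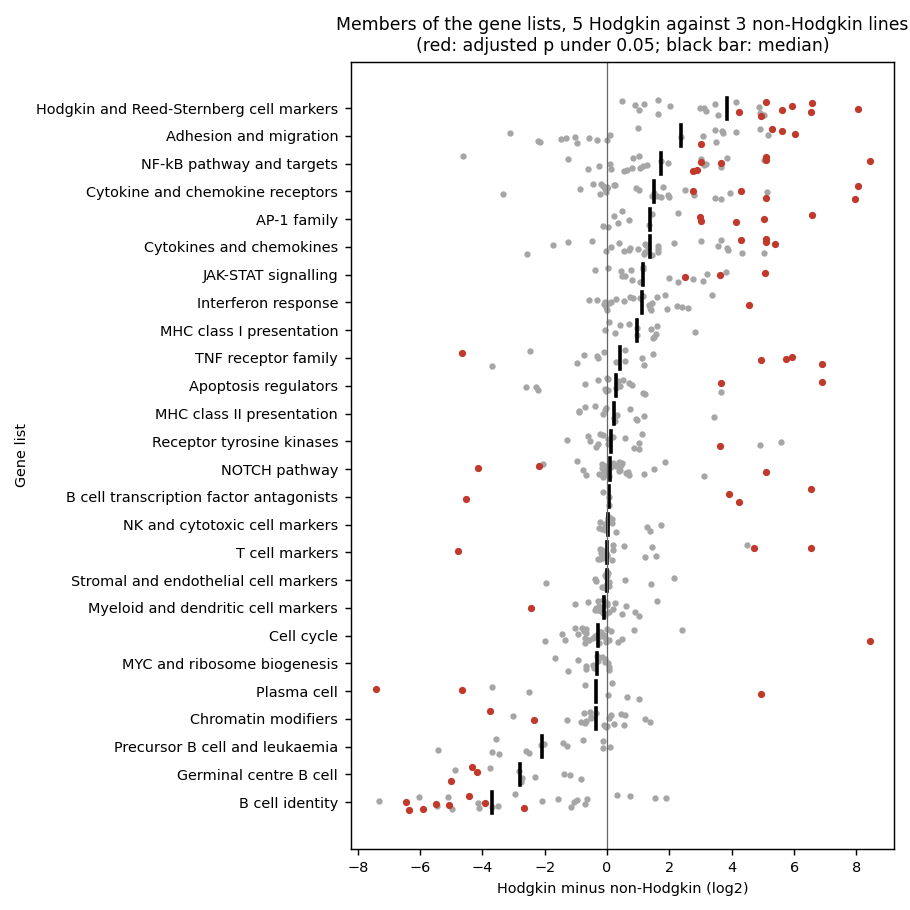
Hodgkin minus non-Hodgkin difference (log2, horizontal axis) of each measured member of the 26 gene lists (rows), with red points for members at adjusted p under 0.05, grey points for the others and a black bar at the list median. Medians run from -3.70 for B cell identity to 3.85 for Hodgkin and Reed-Sternberg cell markers.

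The second question was how far the Hodgkin lines differ from one another, measured against the spread between duplicate cultures. The F test called 8941 of 19740 genes (9473 without Reh replicate 1), 7220 of them with a range of at least 1 log2 over the 5 lines. The share was high in many lists, among them Hodgkin and Reed-Sternberg cell markers (22 of 24) and MHC class I genes (13 of 13). JAK-STAT (17 of 19), MHC class II (13 of 15) and NF-kB genes (25 of 29) were similar. It was low among NK and cytotoxic (4 of 16), stromal (5 of 17) and myeloid genes (8 of 24). The median ranges of these lists were small, at 0.33, 0.36 and 0.53 log2. The median range over the 5 lines was 3.51 log2 for the Hodgkin markers, 3.47 for adhesion genes, 3.14 for cytokines and 2.66 for MHC class II genes.

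L428 was set apart by CTHRC1, 8.11 ± 0.11 log2 above the mean of the other 4 lines (SE, adjusted p = 3.72e-10), and by LRRN3, GNG11, PIK3CG and TSPAN8 (7.01 to 6.64 log2). YBX3 (-7.44), CYTIP (-7.03), HCLS1, TPRG1 and CLIC2 (-5.57) were its largest falls. In all 2124 genes were higher and 2418 lower. L1236 stood out by FCER1A, the alpha chain of the IgE receptor, at 9.66 ± 0.13 log2 (SE, adjusted p = 1.92e-10), BANCR (8.12), IL3 (7.77), NDST4 (7.22) and POU2AF1 (7.03), a B cell coactivator. GSTO1 (-7.39), S100A11, MCUB, TSPYL1 and FAM107B (-6.77) were lower, and 2561 genes were higher and 2002 lower. PAX5 was 4.48 log2 higher in L1236 than in the other Hodgkin lines, and 13 of 15 MHC class II genes were lower and 0 higher there, with HLA-DRA at -2.35 log2. The chemokine genes CCL2 and CXCL10 were 6.50 and 4.59 log2 higher.

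KM-H2 expressed MMP12, a macrophage elastase, 8.78 ± 0.14 log2 above the other lines (SE, adjusted p = 4.18e-10), with TMEM132D-AS1 (8.79), the cancer-testis genes MAGEA4 (8.63) and MAGEA6 (7.74), and CR2 (7.98), the complement receptor of B cells. PERP (-8.09), SCOC, CRNDE, MAP3K13 and P4HA2 (-6.49) were lower, and 2791 genes were higher and 2560 lower. Of the 29 B cell identity genes 9 were higher and 2 lower in KM-H2, among them TCL1A at 4.37 log2, while 13 of 24 Hodgkin markers were lower and 3 higher. CD3D was 2.94 log2 higher. In HDLM2, 16 of 24 Hodgkin markers were higher and 2 lower, with CCL22 at 5.19 log2, and 11 of 15 MHC class II genes were higher and 1 lower. Its largest rises were SOWAHC (7.28 ± 0.13 log2, SE, adjusted p = 3.21e-09), SEPTIN10, PRDX2, SLC1A1 and CLDN14 (6.20), and its largest falls KHSRP (-6.70), CHASERR, MARCKS, ITGAE and WNT5A (-5.62). In total 2439 genes were higher and 2513 lower.

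In L540, taken with its subline, GZMB, a protease of cytotoxic granules, was 7.28 ± 0.20 log2 (SE, adjusted p = 1.25e-08) and NKG7 6.45 log2 above the other Hodgkin lines. Of the 16 NK and cytotoxic cell markers 3 were higher and 1 lower there (median 0.15 log2). ALKAL2 (8.49), G0S2 (7.39) and PDLIM1 (6.50) were also higher, and GNG2 (-7.79), BNIP3, NIBAN1, BASP1 and LY75 (-7.19) lower. Of the 32 cytokine genes 18 were lower, with CCL17 at -5.54 log2, and 3 higher, and 10 of 29 B cell identity genes were lower and 3 higher. In all 2034 genes were higher and 2722 lower. The counts of a line fell when 1 of its 2 arrays was left out, to 2541 and 2309 for L428 (without replicate 1 and 2), 2592 and 2455 for L1236, 3303 and 3318 for KM-H2, and 3198 for HDLM2 without replicate 2.

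L540Cy and L540, with 1 array each, differed in 294 genes, 127 higher and 167 lower in L540Cy. By genes over 1 log2 apart these 2 arrays were about as distant as duplicates of Namalwa or Reh, at 1093 against 1360 and 1171. Over 2 log2 apart were 171 genes, against 64 in Namalwa and 2 to 11 in the duplicated Hodgkin lines. Reh had 258, but its replicate 1 held signal of SU-DHL-4 genes. With 1 array each, the calls cannot be assigned to the lines over single cultures. SLAMF1 (5.79 ± 0.52 log2, SE, adjusted p = 0.000647), DMD, TEX19, GPR84 and PTPN14 (5.02) were the largest rises. ALB, the gene of serum albumin, was lower by -8.57 ± 0.27 log2 (SE, adjusted p = 7.96e-07), at 12.24 in L540 and 3.67 in L540Cy. AFP (-5.64), its fetal relative, GLUL (-5.96), the histone gene H1-2 (-5.60) and IFI44L (-5.50) followed. GZMB was 3.71 log2 higher in L540Cy, and 5 of 33 cell cycle genes were lower (CCNA2, MCM4, MCM7, CCNB2 and MCM6; median of the list -0.59 log2). Of 26 interferon response genes 3 were lower, IFI44L, IFI35 (-2.47) and GBP2 (-2.18), with a median of -1.48 log2 for the list. Without Reh replicate 1, 8 cell cycle and 9 interferon genes were lower. Since the spread comes from other lines, the count depended on them: 466 without either array of Reh, 159 without either array of L428 and 190 without either array of L1236.

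The third question concerned the 3 non-Hodgkin lines, each the single line of its diagnosis. Reh, the precursor line, exceeded both others in precursor B cell genes. DNTT, which adds nucleotides when immunoglobulin genes are assembled, was 8.40 ± 0.50 log2 above SU-DHL-4 (SE, adjusted p = 8.58e-06), and of the 14 precursor genes 9 were higher and 1 lower against either line. PCLO was 9.59 ± 0.22 log2 above Namalwa (SE, adjusted p = 1.39e-08) and 9.46 above SU-DHL-4. Against Namalwa, NRIP1, DUSP6, PTPRK and TSPAN13 (7.69 to 7.30) were also higher and ZNF595 (-8.05), MGST1, LIN28B, KISS1R and UCHL1 (-6.64) lower. Against SU-DHL-4, NRN1, GLUL and IGLL1 (8.28 to 8.01) were higher and RASSF6 (-4.73), SYBU, KCNQ5, PLEKHA8 and PDZRN4 (-3.94) lower. Of 13 MHC class I genes 12 were higher in Reh than in Namalwa and 10 higher than in SU-DHL-4, with 0 lower, and of 26 interferon genes 13 and 14 were higher. The Namalwa arrays themselves differed in the interferon list, with 8 genes over 1 log2 higher in replicate 1 than in replicate 2 and 0 lower.

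SU-DHL-4 exceeded Namalwa in TSPAN13 (7.58 ± 0.47 log2, SE, adjusted p = 1.31e-05), PSMA8, ZNF804A, NELL2 and TRIM9 (6.16), and was lower in YBX3 (-9.32), CRNDE, MGST1, ZNF595 and PLAC8 (-7.49). Of 15 MHC class II genes 8 were higher and 0 lower in SU-DHL-4 than in Namalwa, with HLA-DQB1 at 2.89 log2. Reh and Namalwa differed in 3153 genes, SU-DHL-4 and Namalwa in 1923, and Reh and SU-DHL-4 in 1559. The counts against Namalwa, for Reh and for SU-DHL-4, rose without its replicate 1 and fell without its replicate 2. The higher counts thus came with Namalwa represented by replicate 2 alone, the array with the lowest upper quartile (7.30). Without Reh replicate 1, which held signal of SU-DHL-4 genes, 2850 genes differed between Reh and SU-DHL-4, 3401 between Reh and Namalwa and 2501 between SU-DHL-4 and Namalwa, and RASSF6 was at -6.03 log2. Without it, 11 of 29 B cell identity genes and 8 of 12 germinal centre genes were lower in Reh than in SU-DHL-4 (4 and 2 higher), against 1 and 0 with it (3 and 1 higher).

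**Figure D4:**
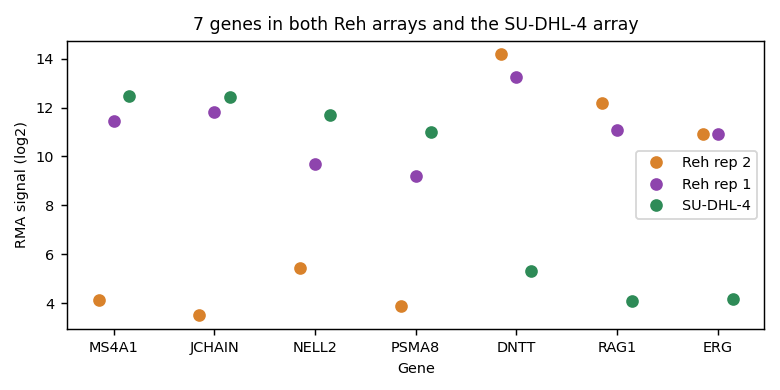
RMA signal (log2, vertical axis) of 7 genes (horizontal axis) in Reh replicate 2, Reh replicate 1 and SU-DHL-4, 1 point per array. MS4A1 is at 4.12 in Reh replicate 2, 11.47 in Reh replicate 1 and 12.48 in SU-DHL-4, while DNTT is at 14.20, 13.25 and 5.32.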

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

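The bounds of the test of other splits of the lines were written after its result was seen. The genes named in the comparison of Hodgkin with non-Hodgkin lines, 77 in all, were examined for a single Hodgkin line far from the other 4, by the gap to its neighbour as a share of the whole range. Genes named only for single lines were chosen because a line stands apart and were not examined. GZMB and NKG7, also named for L540, were examined as the members of the NK and cytotoxic list with the largest differences. In 9 genes, GZMB and NKG7 among them, 1 line lay that far out. Chance gives about 1 in 20, but only for genes not chosen for an outlying line. HDLM2 was highest in ALOX5 (share 0.91, at 4.98 against 3.72 in the next line) and in DOK3 (0.742, 7.48 against 5.54). L428 was highest in RALGPS2 (0.728, 5.43 against 4.43) and lowest in TIMP1 (0.711, 8.96 against 11.11). KM-H2 was highest in CD3D (0.83, 8.60 against 5.94) and in CBFA2T3 (0.777, 5.30 against 4.60). L540 was highest in IRF4 (0.733, 12.53 against 11.88), NKG7 (0.758, 11.69 against 6.32) and GZMB (0.911, 12.01 against 5.07).

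The number of genes called between Hodgkin and non-Hodgkin lines was compared with other ways to part the 8 lines. Of the 56 splits into 5 and 3 lines, 1, the real one, gave as many as its 271 genes, and the highest of the others gave 10. Every other split mixes Hodgkin and non-Hodgkin lines, so the difference between the classes widens its spread and holds its count low. The real split can rank no better than 1 in 56, and Reh replicate 1, which held signal of SU-DHL-4 genes, was kept. This ranking alone does not exclude chance.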

How the results depend on the processing

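None of the 77 named genes changed direction with a call in 1753 recomputed values, of which 1543 stayed on their side of the threshold, 165 lost it and 45 gained it. Without a call, HLA-DQA1, HLA-DQB1, GZMB and CD3D changed sign in at least 1 alternative. Of 58 called named genes, 31 passed under each alternative that tested them. Most losses came with fewer lines: 25 named genes lost their call without Namalwa, 23 without SU-DHL-4, 17 without Reh, 15 without HDLM2, 14 without L1236, 14 without L540, 10 without KM-H2 and 9 without L428. Among the gene lists 383 of 416 values kept their call, 23 lost it, 10 gained it and 0 reversed. The removal of single libraries, the lists under both scalings and the 12 numbered arrays without a block for the line contrasts were chosen after seeing the data. Near the background of the arrays differences are compressed, which limits dim genes. Causes were not tested except where fewer lines or fewer genes were used.

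Counted as 2 lines, L540 and L540Cy gave 233 genes higher and 191 lower against 150 and 121. An array-level fit with the line as a random block gave 599 and 476. It used 1 correlation between arrays of a line, 0.574, for all genes, so such arrays counted partly as independent. Its higher counts are therefore not stronger evidence, and the block fits of the 12 numbered arrays below share this limit. Testing only genes above the median gave 233 higher. Leaving out 1 line gave 68 to 158 higher and 69 to 112 lower. Replicate differences (number 1 minus number 2) correlated over genes at 0.145 to 0.356 in the 10 pairs among L428, L1236, KM-H2, HDLM2 and Reh, and at -0.07 to 0.0574 in the 5 pairs with Namalwa. The duplicates were not taken as pairs, since this correlation did not hold in all lines and the labels name no batch. A measure of RNA quality did shift in all 6 duplicated lines. The 3 prime minus 5 prime signal of ACTB was higher in replicate 1, from 0.519 against 0.368 in L428 to 1.16 against 0.777 in Namalwa. That of GAPDH was higher in replicate 1 in all but L1236 (0.176 against 0.191). A component shared by replicate number, Namalwa included, is left open. With the replicate number as a block, the 12 numbered arrays gave 328 higher and 243 lower, against 416 and 275 without that block. IFITM1 was called in these arrays without the block and not with it (adjusted p = 0.0724). These arrays, which leave out SU-DHL-4, did not call JCHAIN (0.144, and 0.197 with the block), TNFRSF17 (0.203 and 0.277) or LCK (0.0825 and 0.085), nor, without the block, DTX4 (0.0529). The block moved no line contrast by over 1.5 times. L540Cy, L540 and SU-DHL-4 had no numbered arrays, so their contrasts could not be fitted with it. Their ACTB values were 0.497 in SU-DHL-4, below every replicate 1 array, and 0.946 in L540 and 1.22 in L540Cy, above every replicate 2 array. A component of this kind in these lines cannot be told apart from the line itself. One called gene of 271 changed sign with the most variable probe set.

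Centring the arrays moved the median difference of all genes from -0.02 to -0.12 log2. The largest adjusted p over the 16 alternatives was 0.00588 for B cell identity, 0.00936 for germinal centre genes and for Hodgkin and Reed-Sternberg cell markers, 0.212 for precursor genes and 0.322 for the cell cycle. Tested for change in either direction with fry, which compares no list with other genes, 22 of 26 lists passed. With fry in one direction the TNF receptor (adjusted p = 0.00191), myeloid (0.014) and chromatin (0.0315) lists passed, and the precursor (0.0621), MHC class I (0.0731), MYC (0.0731) and cell cycle (0.315) lists did not. With an estimated correlation 7 lists were higher and 2 lower, against 11 and 5. Leaving out 1 line gave 10 to 11 lists higher and 3 to 6 lower, the lowest without Reh. Asking for at least 1 log2 gave 2127 genes for L428, 2035 for L1236, 2594 for KM-H2, 2334 for HDLM2, 2248 for L540 and 1934 for Reh against Namalwa. Leaving out 1 array gave 2309 to 5107 for L428, 2455 to 5097 for L1236, 3303 to 5906 for KM-H2, 3198 to 5479 for HDLM2, 159 to 466 for L540Cy against L540, 2298 to 4760 for Reh against Namalwa, 1460 to 3095 for SU-DHL-4 against Namalwa and 1079 to 2850 for Reh against SU-DHL-4.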

Other observations

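The 2 cultures of Namalwa differed in interferon response genes, among others: 8 of 26 were over 1 log2 higher in replicate 1 and 0 were lower, with a median difference of 0.48 log2. In the germinal centre list 5 of 12 were over 1 log2 higher and 1 lower (median 0.56 log2). Of 16 NK and cytotoxic genes 0 were higher and 3 lower (median -0.44 log2). The upper quartile of all probe sets was 7.59 in replicate 1 and 7.30 in replicate 2. Duplicates of Namalwa had 1360 genes over 1 log2 apart, against 45 in L428 and 1171 in Reh. No explanation was tested.

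The tests below were chosen after the patterns were seen, and their bounds were written after the results were at least partly known, except that of RNA quality, which was written before. The array labelled Reh replicate 1 carried genes of SU-DHL-4: of 22 genes specific to SU-DHL-4, 21 were over 1 log2 higher in it than in Reh replicate 2, with a median of 32.4% of the linear SU-DHL-4 signal. A changed state of the Reh culture is argued against, since of 239 genes over 2 log2 higher in Reh replicate 1, 99.6% were also over 1 log2 higher in SU-DHL-4 than in Reh replicate 2, against 2.71% of other genes as low. An array of another line under the name Reh is argued against too, since 55 genes that only Reh replicate 2 expressed among the other arrays lay a median of 3.995 log2 above SU-DHL-4 in replicate 1. RNA or cells of SU-DHL-4 in the sample may be the source: those 55 genes had a median of -0.977 log2 in replicate 1 against replicate 2, below the lowest of the 5 other duplicated lines (-0.333). Whether cultures or RNA were mixed was not tested.

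Albumin (ALB, 12.24) and alpha-fetoprotein (AFP, 10.59) were high in the L540 array alone, against at most 3.92 and 5.42 in the other 14, L540Cy included. RNA of liver cells is argued against, since the highest excess of 15 other liver genes over the highest other array was 0.0666 log2. A fault of single probe sets is argued against for ALB, since L540 was highest in all 4 of its probe sets, by 0.889 to 8.32 log2, against at most 0.509 log2 between duplicates of a line; the bound first written, 1 log2 in each probe set of both genes, was missed by 1 of them. It stays open for AFP, which has 1 probe set (excess 5.17 log2). The genes are neighbours in the RefSeq order of GRCh38.p14, and AFM, the next gene, was at 3.72 in L540, within the other arrays (3.50 to 3.93), and with 1 array of L540 no biological explanation was tested.

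Histone genes were lower in L540Cy than in L540: of 42 measured, 36 were lower and 20 by over 1 log2, with a median of -0.79 log2. None of 10000 random lists matched on mean signal had a median as low (lowest -0.228), which describes these 2 arrays only. The lists were drawn gene by gene and do not allow for genes that move together, so they cannot say how unusual this median is. As replicate 1 minus replicate 2, the histone median ran from -0.05755 log2 in HDLM2 to 0.338 in KM-H2 and 0.3775 in L1236 over the duplicated lines. By array, the histone median was 6.28 in L540 and 5.43 in L540Cy, against 5.04 to 5.62 in the other arrays. The L540 array thus stood apart, while L540Cy lay among the other lines. For RNA quality the bound was not reached. The 3 prime minus 5 prime signal of ACTB differed by 0.277 log2 between L540 and L540Cy and by up to 0.38 between duplicates (GAPDH: 0.00759 and 0.0822). L540Cy nevertheless had the highest ACTB value of all arrays (1.22, against 0.946 in L540). The bound came from Namalwa and holds a shift between replicates 1 and 2 seen in every duplicated line. It therefore cannot decide, and a difference in RNA quality is left open. A difference between the 2 cultures in the share of cells in S phase remains a candidate explanation. As L540Cy minus L540, 17 S phase genes had a median of -1.04 log2. Of these, 9 also stand in the cell cycle list whose calls had been seen. The S phase genes were not compared with the other arrays, so which of the 2 cultures was unusual in them was not tested.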
